A study of Caulobacter vibrioides NA1000 with 8 samples.

How the data were processed

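RNA was measured in 2 strains of Caulobacter crescentus NA1000, with APEX2 on full-length RNase E or on RNase E without its C-terminal domain, each as 2 cultures. Per the labels' protocols, an aliquot of each culture's lysate was kept beside the streptavidin eluate of biotin-coupled RNA, and libraries were made with a TruSeq kit. The 8 libraries are 4 eluates and 4 lysates. Strandedness is not given in the sources used here, so an RNA and its antisense partner cannot be told apart. Bowtie is named in the submitters' processing notes without a version. The build named by the submitters is not given in the sources used here.

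The values are log2 ratios of eluate to lysate that the authors deposited, 1 column per culture. How the authors scaled libraries, set a minimum for giving a ratio, or treated reads that match several places is not given in the sources used here. Of 4115 rows, 1 was blank and was left out. Cells without a ratio were treated as missing and not as 0. Both cultures of a strain had ratios for the same RNAs, 1207 with full-length RNase E and 2183 in the ΔCTD strain. Why a ratio is missing is not known, and it may or may not relate to the level of an RNA. No level was therefore read from a missing ratio, and 1915 RNAs had none in either strain. The values hold no counts, so depth is unknown, no interval for counting error could be given, and precision was taken from the spread between cultures alone. The cultures are biological replicates per the labels' design text.

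Locus tags of 4057 rows matched a RefSeq gene table of assembly ASM2200v1, and 4040 of them had the same start and end there, so coordinates are printed for protein-coding genes and small RNAs. Coordinates of tRNA and rRNA genes are left out, since those of tRNA rows did not match. No genome sequence was used.

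The design written before the data were examined named a count test, with limma on log2 ratios as the test should only ratios be at hand, and the latter was used. limma 3.58.1 in R 4.3.3 was fitted to the 4 columns with a mean per strain, moderated with eBayes and adjusted by the Benjamini-Hochberg method at 0.05. Contrasts were each strain's mean against 0, and the full-length mean minus the ΔCTD mean for the 1191 shared RNAs. With the values as deposited, the estimated prior degrees of freedom were infinite, so every RNA got 1 spread (SD 0.138) and an SE of 0.0973 for a strain mean and 0.138 for a difference. After each culture was centred on its median over the shared RNAs, the prior had 4.58 degrees of freedom and an SD of 0.0889. This second scale was chosen after the values had been seen, and it assumes that the median RNA did not change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

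RNAs were named by a rule fixed before the data were examined. It took, per comparison, the 10 highest and 10 lowest among those past the threshold with the same sign in every culture, then rne, 27 fixed genes and RNAs, and the 2 largest and 2 smallest members of each called list. Its minimum abundance could not be applied to ratios. Of the 27 fixed names 21 were in the table, 16 with full-length and 18 with ΔCTD ratios. Of these, the RNase P RNA (rnpB, CCNA_R0061) and the signal recognition particle RNA (ffs, CCNA_R0005) have no symbol in the gene table and were matched by RNA type. Examples outside the rule were chosen after their values were seen: cdzA, and CCNA_R0042 in the difference between strains.

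Gene lists were planned by product name, symbol or RNA class. Product names were not used here, so ribosomal proteins, aminoacyl-tRNA synthetases, translation factors, RNA polymerase and sigma factors, ATP synthase, respiratory chain, flagellum and chemotaxis, and toxin-antitoxin genes were matched by symbol patterns written after the values were at hand. Genes without a symbol stood in for hypothetical proteins. Lists matched by symbol leave out any member without one, and 3220 coding genes had none. Degradosome and RNA decay, cell cycle regulators, chaperones and proteases, oxidative stress and the tricarboxylic acid cycle were planned by symbol. Lists of cell division and peptidoglycan, outer membrane assembly and Tol-Pal, DNA replication and repair, S-layer, bacteriocin cdz, and polar pili and holdfast were added after values had been explored. Planned lists of TonB-dependent receptors, two-component signalling, transcriptional regulators, transposons and phages, and transporters were not analysed here. The 15 lists with at least 5 shared members were tested over the shared RNAs with camera at a preset correlation of 0.01, and again with an estimated correlation. These camera tests used the values as deposited unless stated. The lists were also tested with fry on the centred values. It asks whether a list moves on balance one way, here relative to the median of the shared RNAs.

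The steps were tested on simulated ratios. In the full-length contrast, simulated changes of 0.25, 0.5 and 1 were recovered for 41.8%, 100% and 100% of changed RNAs among 1207, with 9 unchanged RNAs called. For the difference between strains the shares were 8.96%, 86.6% and 100% among 1191, with 7 unchanged RNAs called. A list moved by 0.3 was called, and 0 of 20 unmoved lists were. The simulated RNAs were independent, with 1 common spread and no shift of whole cultures. These shares therefore do not show how often calls are false, or changes recovered, where RNAs are correlated or differ in spread.

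Alternatives were a 2-fold minimum, leaving out rRNA and tRNA, leaving out each culture, centring, values relative to 23S and 16S rRNA, shared RNAs alone, robust moderation (which returned the same values throughout), a replicate block and a fit per strain. Comparisons of lysates, RNA class shares and abundance need counts and were not made.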

Results

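The data address which RNAs lie close to RNase E in the bacterium Caulobacter crescentus (strain NA1000). RNase E is the endoribonuclease that starts the decay of many bacterial messenger RNAs, and its C-terminal domain carries binding sites for other decay enzymes. The peroxidase APEX2 was fused to full-length RNase E or to RNase E lacking the C-terminal domain (the ΔCTD strain). Cells in M2G minimal medium at an OD600 of 0.3 to 0.6 received an alkyne phenol for 30 min and hydrogen peroxide for 1 min, so that molecules near the peroxidase were labelled. Labelled RNA was coupled to biotin and pulled down on streptavidin, which gave an eluate beside the lysate of the same culture. There were 2 cultures per strain and 8 sequenced libraries in all, 4 eluates and 4 lysates. None came from cells without APEX2, phenol or peroxide, so the background of the pull-down was not measured and enrichment is not by itself proof of closeness. The values are the log2 ratio of eluate to lysate, so a value of 1 is a 2-fold enrichment over the lysate on the deposited scale. How the libraries were scaled is not given in the sources used here, so the value that stands for no change is uncertain. Enriched and depleted below refer to the sign of the deposited ratio. Read counts are not part of the values used here, so the depth behind each ratio is unknown. The spread between cultures is the only error measured. Of the RNAs named below, the rows of rne, rplS, pleD, divK, flbT, the cdz genes, CCNA_01043, CCNA_01834, CCNA_01944, CCNA_03786, CCNA_03985, CCNA_R0098, CCNA_R0118 and CCNA_R0119 each overlap 1 other row and that of CCNA_01995 overlaps 2, so their values are uncertain.

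Of 4114 named rows, 1207 had ratios in both full-length cultures and 2183 in both ΔCTD cultures. Ratios in both strains were given for 1191 rows, called shared RNAs here, of which 1178 were protein-coding. Within a strain the cultures resembled each other, with a Pearson correlation across genes of 0.88 for the full-length pair and 0.76 for the ΔCTD pair. Genes are not independent replicates, so these correlations carry no p-value. Between strains the correlation over the shared RNAs was 0.06 and 0.04 with ΔCTD culture 1, and 0.27 and 0.24 with ΔCTD culture 2. Once the median difference between the 2 cultures of a strain was removed, ratios of a single RNA varied with an SD of 0.10 in the full-length strain. In the ΔCTD strain this SD was 0.11. The fit of the values as deposited, which keeps that shift, used an SD of 0.138.

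As deposited, most of the messenger RNAs with a ratio lay above 0 in the eluates of full-length RNase E. The shared RNAs as a whole had lower ratios in the ΔCTD eluates. Only 1193 of 3885 coding genes (30.7%) had a full-length ratio, and nothing is known here of the others. The median ratio over the shared RNAs was 0.44 and 0.52 in the full-length cultures and 0.05 and 0.14 in the ΔCTD cultures. The mean of these medians was 0.48 ± 0.05 (SD, n = 2), a 1.40-fold enrichment, against 0.10 ± 0.07 (SD, n = 2), or 1.07-fold. Ratios were above 0 for 96.4% and 95.7% of the shared RNAs in the full-length cultures and for 63.3% and 75.9% in the ΔCTD cultures. The rows for 23S rRNA stood at 0.01 and -0.01 with full-length RNase E and at -0.02 and -0.08 in the ΔCTD strain. The rows for 16S rRNA stood at -0.07 and -0.03, and at 0.03 and 0.09. A second 23S rRNA row stood at 0.32 and 0.09 with full-length RNase E and at 0.58 and 0.30 in the ΔCTD strain. With 2 cultures against 2, an exact permutation test of the medians cannot go below 1/3. Because this shift moves almost every RNA, changes of single RNAs are also given below relative to the median of the shared RNAs in the same culture, called centred values.

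**Figure D1:**
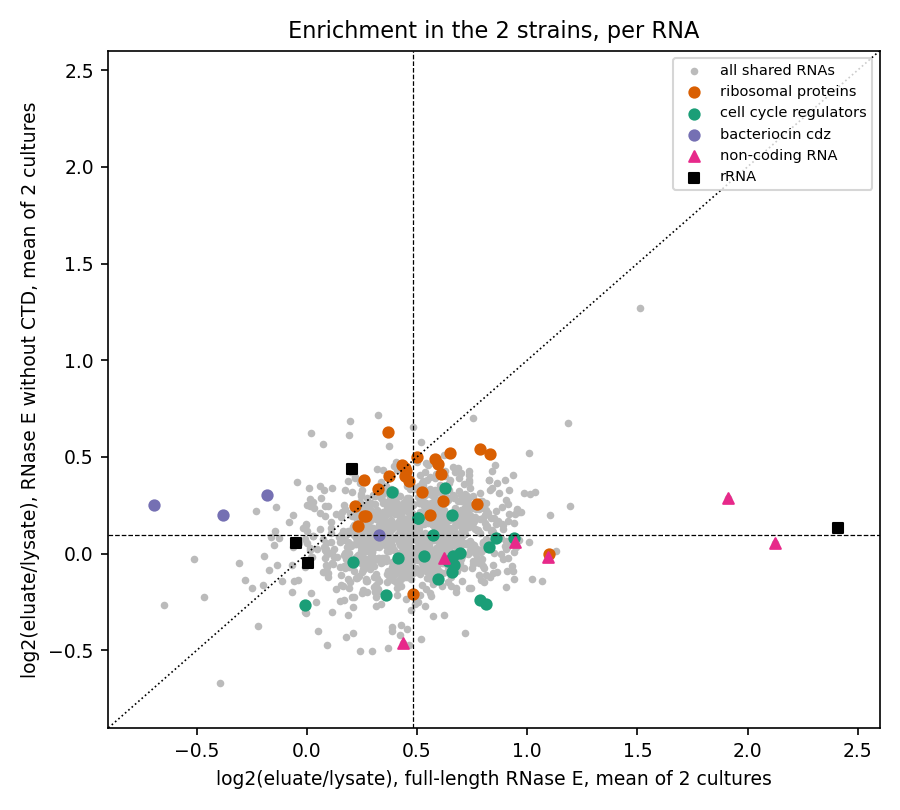
Each point is an RNA with ratios in both strains, placed by its mean log2 ratio of eluate to lysate over 2 cultures with full-length RNase E (x axis) and with RNase E without its C-terminal domain (y axis). Dashed lines mark the strain medians of 0.48 and 0.10, the dotted line marks equal values, and 5S rRNA, CCNA_R0077 and CCNA_R0088 lie far to the right at 2.41, 2.13 and 1.91.

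The first question was which RNAs are found near full-length RNase E. The message of rne itself (CCNA_01954, positions 2097480 to 2100176 of the NA1000 chromosome, assembly ASM2200v1) had ratios of 0.45 and 0.46, close to the median RNA. The highest ratio belonged to 5S rRNA, which RNase E is known to release from its precursor in Escherichia coli, at 2.41 ± 0.45 (SD, n = 2). Next came the small RNAs CCNA_R0077 (3532896 to 3533067) at 2.13 ± 0.13 (SD, n = 2), which is 4.36-fold, and CCNA_R0088 (3946037 to 3946176) at 1.91 ± 0.18 (SD, n = 2), which is 3.76-fold. Among messenger RNAs the top ratios were those of CCNA_03303 at 1.51, CCNA_00699 at 1.20, CCNA_00839 at 1.18, CCNA_01834 at 1.13, pssZ at 1.10 and rplS, the gene of ribosomal protein L19, at 1.10. The small RNA CCNA_R0123 stood at 1.09. All of these passed the limma test as deposited and relative to the median, with relative values from 0.61 for CCNA_R0123 (adjusted p = 0.029) to 1.93 for 5S rRNA. The 5S, 16S and 23S rRNA genes have near-identical copies, so their rows are uncertain.

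Few RNAs were called lower in the full-length eluates as deposited (14), against 274 relative to the median. The lowest was cdzC, from the operon of a contact-dependent bacteriocin, at -0.69 ± 0.06 (SD, n = 2). It was followed by CCNA_03984 at -0.65, CCNA_01944 at -0.51, CCNA_01221 at -0.46, flbT, a regulator of flagellin message stability, at -0.39, and cdzI, the bacteriocin immunity gene, at -0.38 ± 0.22 (SD, n = 2). The RNA chaperone gene hfq stood at -0.31, glnB, a nitrogen-status signalling protein gene, at -0.29, CCNA_03820 at -0.28 and CCNA_00530 at -0.25. Each of these 10 was below 0 in both cultures, and each also passed the limma test relative to the median, with values from -0.73 for CCNA_00530 to -1.18 for cdzC. As deposited, 4 of them did not pass with a culture left out, namely cdzI without culture 1 (-0.23) and CCNA_03820 (-0.079), CCNA_00530 (-0.21) and glnB (-0.24) without culture 2.

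Of the 5 measured genes of the degradosome and RNA decay list, 4 were higher and hfq was lower as deposited, and adjusted over the list alone all 5 passed. Relative to the median, rhlB, a helicase of the degradosome, was higher at 0.24 (adjusted p = 0.033) and hfq was lower at -0.79 (adjusted p = 0.0011). The messages of rne at -0.03, pnp (polynucleotide phosphorylase) at 0.04 and acnA (aconitase, a degradosome partner in this species) at -0.00 did not pass. The list was not called (camera, adjusted p = 0.69).

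Of 22 measured cell cycle regulators, 21 were higher in the full-length eluates as deposited and adjusted over the list alone, and relative to the median 9 were higher, 2 lower and 11 not called. The message of popZ, a polar organizing protein, reached 0.83, or 0.34 (adjusted p = 0.0063) relative to the median. The master regulator gene ctrA stood at -0.01, which is -0.49 relative to the median (adjusted p = 0.004). Values for ccrM (0.60), sciP (0.63), gcrA (0.50), dnaA (0.42) and ftsZ (0.36) passed as deposited and did not pass relative to the median, where those of dnaA and ftsZ were -0.07 and -0.12. As a list, the regulators were not called in this strain (camera, adjusted p = 0.44). Outside the list, pilA, the polar pilin, was higher on both scales at 0.93 and 0.45 (adjusted p = 0.0029). So was katG (catalase-peroxidase) at 0.74 and 0.25 (adjusted p = 0.018). The chaperone gene dnaK at 0.46 and the S-layer gene rsaA at 0.55 were -0.03 and 0.07 relative to the median and did not pass there.

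Only 7 of 126 non-coding RNA rows (5.56%) had a full-length ratio, and nothing is known here of the others. All 7 were higher as deposited and adjusted over the list alone. After centring 5 were higher and 2 were not called, namely CCNA_R0042 at -0.05, annotated as antisense and uncertain since strandedness is not stated, and the RNase P RNA CCNA_R0061 at 0.14. Over the shared RNAs this was the 1 list of 15 called in this strain with the preset correlation (camera on 6 members, adjusted p = 3.65e-09). On centred values the same test gave a much weaker adjusted p = 0.024, and with an estimated correlation the list was not called (adjusted p = 0.80). Only 3 of 94 tRNA rows had ratios in the full-length strain. Their median was 0.09, none passed as deposited or adjusted over the list alone, and relative to the median all 3 were lower.

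In all, limma called 1060 RNAs higher and 14 lower of 1207 tested in the full-length strain. After centring the split was 246 higher and 274 lower, and 16 higher and 0 lower also had at least a 2-fold change as deposited. The share of higher calls was 98.7% as deposited and 47.3% relative to the median. One spread for every RNA was used by the fit of the values as deposited, so its smallest p-values understate the uncertainty of an RNA such as 5S rRNA, whose cultures differed by more.

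The next question was which RNAs remain near RNase E without its C-terminal domain. The rne message was enriched at 0.38 in both cultures, or 0.28 relative to the median (adjusted p = 0.024). The highest ratios were those of the small RNA CCNA_R0118 at 0.86 and 2.32, a tRNA for glutamate (anticodon TTC) at 1.17 and 1.95, and CCNA_03303 at 1.27 ± 0.05 (SD, n = 2). The small RNA CCNA_R0118 has a second row, CCNA_R0118_808926, with nearly the same ratios, 0.87 and 2.31, and both overlap, so they are uncertain. Further down were the small RNA CCNA_R0119 at 0.84, CCNA_02088 at 0.80, CCNA_01445 and CCNA_03985 both at 0.72, the signal recognition particle RNA CCNA_R0005 at 0.71 and btuB, a cobalamin receptor gene, at 0.70. Several of these rest on unequal cultures, and without culture 2 the values were 0.86 for CCNA_R0118, 0.39 for CCNA_03985 and 0.32 for CCNA_R0005, which stood at 1.11 without culture 1. All passed the limma test on both scales.

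The lowest ratios of the ΔCTD strain were those of flbT at -0.67 ± 0.19 (SD, n = 2), CCNA_01749 and CCNA_03587 at -0.50, CCNA_00808 at -0.49, CCNA_03030 at -0.47 and a leucine tRNA (anticodon GAG) at -0.47. They were followed by pbpZ, a penicillin-binding protein gene, at -0.47, CCNA_R0042 at -0.46, CCNA_02906 at -0.44 and dksA, a regulator of transcription, at -0.43. Each passed on both scales. The message of flbT was thus depleted with either form of RNase E.

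Messages of ribosomal proteins had a median ratio of 0.39 in the ΔCTD strain, against 0.10 for the shared RNAs. With full-length RNase E their median was 0.47 and the list was not called (camera, adjusted p = 0.81). Of 26 members, 20 were higher as deposited and 6 were not called, and adjusted over the list alone 22 passed. After centring 16 were higher, 1 was lower and 9 were not called. The largest values were rplP at 0.63 ± 0.09 and rpsH at 0.54 ± 0.05, and the smallest were rpsU at -0.21 ± 0.00 and rplS at -0.00 ± 0.07 (SD, n = 2 each). Over the shared RNAs this was the 1 list of 15 called in the ΔCTD strain with the preset correlation (camera, adjusted p = 9.7e-09), and with an estimated correlation it was not called (adjusted p = 0.99). Of these 26 genes, 24 lie within 14.55 kb (1431343 to 1445888), so they are not independent measurements. The list holds only genes with a symbol, and 3220 coding genes have none. Any ribosomal protein genes among those are missing from it.

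**Figure D2:**
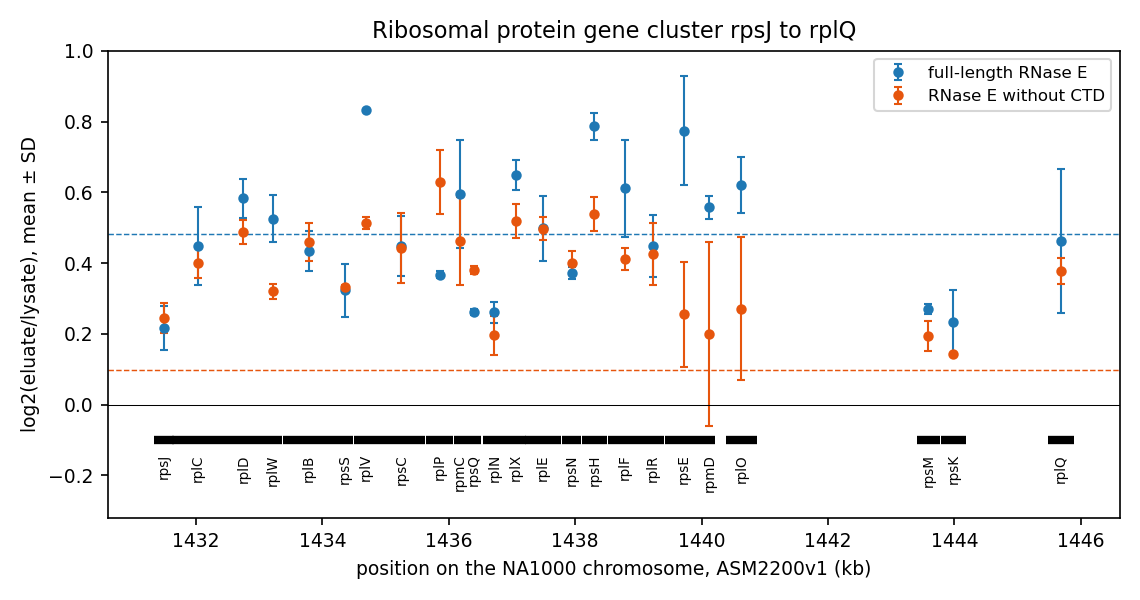
Mean log2 ratio of eluate to lysate with SD over 2 cultures (y axis) of the 24 ribosomal protein genes from rpsJ to rplQ, by position on the NA1000 chromosome in kb (x axis, black bars are the genes), for full-length RNase E (blue) and RNase E without its C-terminal domain (orange). Dashed lines are the strain medians of 0.48 and 0.10, and the median of these genes is 0.46 in the full-length strain and 0.40 in the ΔCTD strain.

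Among RNA decay genes of the ΔCTD strain, acnA was higher at 0.65 ± 0.05 (SD, n = 2; 0.55 relative to the median, adjusted p = 0.013) and pnp at 0.36 (0.26 relative to the median, adjusted p = 0.027). Ratios of rhlB (0.05) and hfq (-0.05) did not pass. Of the 5 members, 3 passed as deposited, adjusted over the list alone and relative to the median, and the list was not called (camera, adjusted p = 0.16). Of 26 cell cycle regulators, 3 were higher, 3 lower and 20 not called as deposited, and 6 passed adjusted over the list alone. Relative to the median 1 was higher and 7 were lower, among them ctrA at -0.36 (adjusted p = 0.024), ftsZ at -0.31 (adjusted p = 0.018) and divK, measured in this strain alone, at -0.32 (adjusted p = 0.027). The list itself did not pass (camera, adjusted p = 0.16). Values that did not pass on either scale were those of dnaA (-0.02), ccrM (-0.13), popZ (0.03), gcrA (0.19), pilA (-0.06), katG (0.14) and dnaK (0.22), though gcrA and dnaK passed as deposited in a fit of the shared RNAs alone. The messages of sciP at 0.34 and rsaA at 0.31 passed as deposited and were 0.24 and 0.21 relative to the median, short of the threshold. As deposited, sciP (0.18), rsaA (0.25) and ctrA (-0.20) did not pass without culture 2, where divK (-0.33) passed, and dnaK (0.29) passed without culture 1.

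In the ΔCTD strain 14 of 94 tRNA rows had ratios. Of these, 8 were higher and 2 lower as deposited, with a median of 0.32, and 11 passed adjusted over the list alone. With centred values 7 were higher and 3 lower. Ratios were given for 19 of 126 non-coding RNA rows. Of these, 9 were higher and 1 lower as deposited, 10 passed adjusted over the list alone, and relative to the median 7 were higher and 1 lower. The RNase P RNA CCNA_R0061, at -0.02, did not pass on either scale. Over the 6 shared non-coding RNAs the list lay below other genes without passing (camera, adjusted p = 0.40), and over all RNAs measured in this strain it lay above them (adjusted p = 5.015e-06), though not with an estimated correlation (adjusted p = 0.99). These 19 members hold both rows of CCNA_R0118, and with 1 row per RNA the adjusted p was 0.00257.

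In all, 449 RNAs were called higher and 83 lower of 2183 tested in the ΔCTD strain, and relative to the median 217 and 246. The share of higher calls was 84.4% as deposited and 46.9% relative to the median, and 4 higher and 0 lower RNAs also changed at least 2-fold. Culture 2 carried much of the count, since 135 RNAs were called higher without it and 600 without culture 1.

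The main question was which ratios depend on the C-terminal domain, tested for each shared RNA as the full-length ratio minus the ΔCTD ratio. The rne message differed by 0.08 (SE 0.14) and did not pass (adjusted p = 0.62), and its centred difference was -0.31 (adjusted p = 0.036). The largest differences were 5S rRNA at 2.28, CCNA_R0077 at 2.07 and CCNA_R0088 at 1.63 (3.08-fold), each with an SE of 0.14. Also among the highest 10 were lovR (297735 to 298193), a response regulator gene, at 1.21 and rplS at 1.10. CCNA_01995 at 1.15, CCNA_03400 at 1.13, CCNA_01834 at 1.12, the small RNA CCNA_R0123 at 1.11 and CCNA_03786 at 1.08 were the others. Each full-length culture lay above each ΔCTD culture for all 10. After centring, 9 of them passed the limma test, from 0.69 for CCNA_03786 to 1.89 for 5S rRNA. CCNA_R0123, whose ΔCTD cultures were -0.48 and 0.44, was at 0.73 and did not pass (adjusted p = 0.065), and as deposited it fell to 0.65 without ΔCTD culture 1.

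**Figure D3:**
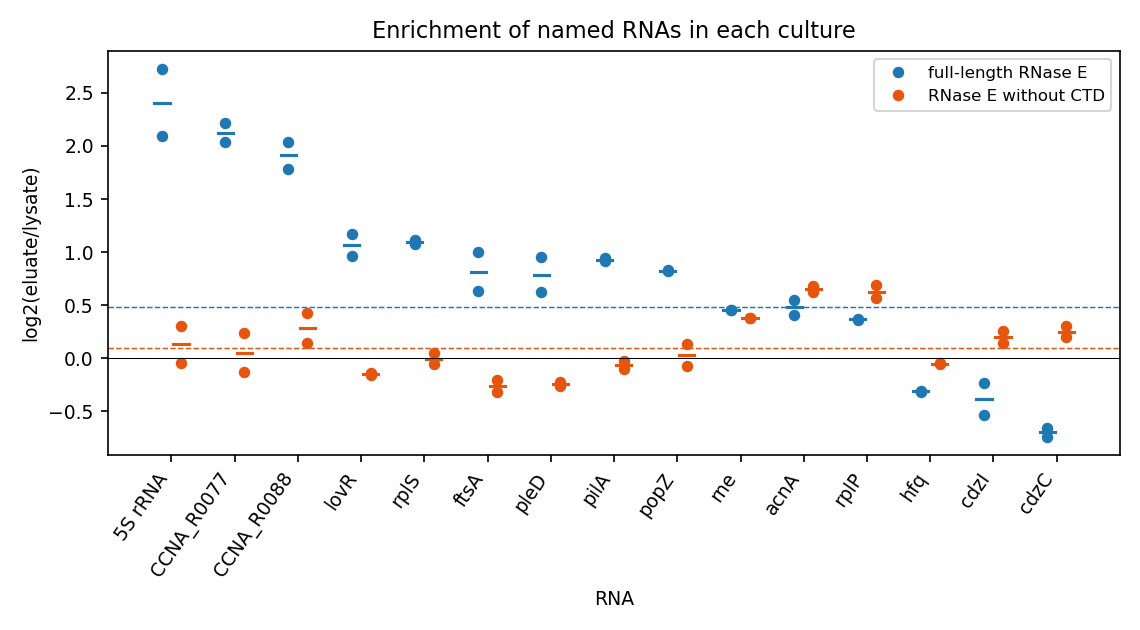
Log2 ratio of eluate to lysate (y axis) of 15 named RNAs (x axis) in each of 2 cultures with full-length RNase E (blue) and 2 with RNase E without its C-terminal domain (orange). Points are cultures, short bars their means and dashed lines the strain medians of 0.48 and 0.10. The cdzC message is below 0 in the full-length cultures at -0.65 and -0.74 and above 0 in the others at 0.31 and 0.20.

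Ratios were lower with full-length RNase E for 14 RNAs, 3 of them from the bacteriocin operon. This count was 27 in a fit of the shared RNAs alone and 35 with a replicate block. The difference was -0.95 (SE 0.14) for cdzC, -0.58 for cdzI and -0.48 for cdzD. The others of the lowest 10 were CCNA_01043 at -0.60, CCNA_02763 and CCNA_03553 at -0.49, CCNA_01944 at -0.48, CCNA_03703 at -0.45, CCNA_02817 at -0.42 and CCNA_03995 at -0.41. Each had both full-length cultures below both ΔCTD cultures and passed on both scales. As deposited, CCNA_02817 (-0.36) did not pass without full-length culture 2, nor CCNA_03995 (-0.24) without full-length culture 1, and CCNA_03553 was at -0.30 without ΔCTD culture 2. Of the 4 cdz genes measured in both strains, cdzA, a gene of the secretion apparatus, did not pass at 0.24 (adjusted p = 0.12).

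Cell cycle regulators had a median difference of 0.62, against 0.37 over all shared RNAs. The list lay above other genes with the preset correlation (camera, adjusted p = 0.0104) and was not called with an estimated correlation (adjusted p = 0.96). Of 22, 18 had a higher ratio with full-length RNase E and 4 were not called, 19 passed adjusted over the list alone, and after centring 9 were higher and 0 lower. The largest were ftsA (cell division) at 1.08 and pleD (a diguanylate cyclase) at 1.03, and the smallest were cpdR at 0.07 and mucR2 at 0.25, which did not pass. The difference was 0.79 for popZ, 0.73 for ccrM, 0.57 for ftsZ, 0.44 for dnaA and 0.32 for gcrA. Of these, popZ (0.41) also passed relative to the median, and gcrA turned to -0.07 there. The pilin gene pilA, which is not in this list, differed by 0.99, or 0.61 relative to the median, and passed on both scales. Values of 0.29 for sciP and 0.26 for ctrA did not pass on either scale, though both, and mucR2, passed as deposited in a fit of the shared RNAs alone. With a culture left out, gcrA did not pass without full-length culture 1 (0.30) or 2 (0.33), while sciP (0.45, without ΔCTD culture 2) and ctrA (0.32, without ΔCTD culture 1) passed as deposited.

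Ribosomal protein messages had a median difference of 0.09, the least of the 3 called lists. The list lay below other genes with the preset correlation (camera, adjusted p = 0.00645) and was not called with an estimated correlation (adjusted p = 0.96). Of 26 members, 6 had a higher ratio with full-length RNase E and 20 were not called, and 3 passed adjusted over the list alone. With centred values, 14 were lower and 2 higher. The largest were rplS at 1.10 and rpsU at 0.69, and the smallest were rplP at -0.26 and rpsQ at -0.12, both lower relative to the median at -0.65 and -0.50. Without ΔCTD culture 1 rplP passed as deposited at -0.33, and it also passed in a fit of the shared RNAs alone. All 6 shared non-coding RNAs, of 126 rows of this class, were higher, also adjusted over the list alone, 4 of them relative to the median too. For this list camera gave adjusted p = 1.66e-10 as deposited, 0.00059 on centred values and 0.70 with an estimated correlation. Among the 6 were CCNA_R0098 at 0.88, CCNA_R0042 at 0.90 and the RNase P RNA CCNA_R0061 at 0.65. The last of these did not pass relative to the median at 0.26.

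Of the 5 RNA decay genes, rhlB alone passed as deposited, at 0.67, and relative to the median it stood at 0.29 (adjusted p = 0.073). Relative to the median, acnA (-0.56, adjusted p = 0.0081), hfq (-0.65, adjusted p = 0.0081) and rne were lower, and pnp at -0.22 did not pass. Adjusted over the list alone, 1 passed as deposited. The list was not called (camera, adjusted p = 0.14). The katG difference of 0.60 passed as deposited and stood at 0.21 relative to the median. Differences of 0.23 for dnaK and 0.24 for rsaA did not pass, though both did without ΔCTD culture 2 (0.30 and 0.31), as did rsaA without full-length culture 1 (0.37). In a fit of the shared RNAs alone rsaA and hfq (-0.26, lower) passed as deposited.

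In all, 728 RNAs had a higher and 14 a lower ratio with full-length RNase E, of 1191 tested. With centred values the split was 153 and 179, the share of higher calls fell from 98.1% to 46.1%, and 15 higher and 0 lower RNAs differed by at least 2-fold as deposited.

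Other tested lists were not called in any of the 3 comparisons (camera, adjusted p from 0.22 to 0.97), which does not show that they matched other genes. The median difference was 0.27 for 20 respiratory chain genes, 0.30 for 18 flagellum and chemotaxis genes, 0.19 for 6 aminoacyl-tRNA synthetase genes and 0.47 for 5 genes of RNA polymerase and sigma factors. It was 0.49 for 10 chaperone and protease genes, 0.32 for 5 genes of the tricarboxylic acid cycle and 0.38 for 859 coding genes without a symbol. As deposited, higher ratios with full-length RNase E were called for 8 respiratory chain, 10 flagellum and chemotaxis, 2 synthetase, 3 RNA polymerase and sigma factor, 7 chaperone and protease, 3 cycle and 534 symbol-less genes, and lower ratios for 11 symbol-less genes. Adjusted over the list alone, the genes called in either direction numbered 8, 8, 2, 3, 7, 3 and 546. After centring, 1 was higher and 7 were lower for the respiratory chain, 0 and 2 for the synthetases, and 1 and 0 for chaperones and proteases. The centred counts were 2 and 3 for flagellum and chemotaxis, and 1 and 2 for RNA polymerase and sigma factors. For the tricarboxylic acid cycle they were 1 and 1, and for symbol-less genes 109 and 116. Lists with under 5 measured members had a median difference of 0.14 (2 translation factors), 0.24 (2 ATP synthase genes), 0.03 (2 toxin-antitoxin genes) and 0.54 (2 oxidative stress genes), and of these only the 2 oxidative stress genes passed as deposited and adjusted over the list alone. The median difference of 3 tRNAs was 0.05, with 1 higher, and that of 4 rRNA rows was -0.03, with 5S rRNA alone called as deposited. After centring, higher and lower calls numbered 0 and 1 for the tRNAs and 1 and 3 for the rRNA rows. Neither oxidative stress gene passed after centring, and 1 toxin-antitoxin gene was lower.

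Further lists were chosen after the values had been seen. The median difference was 0.49 for 19 cell division and peptidoglycan genes (14 higher), 0.40 for 12 genes of outer membrane assembly and the Tol-Pal system (7 higher), 0.40 for 13 DNA replication and repair genes (10 higher), 0.40 for 5 S-layer genes (4 higher) and 0.20 for 4 genes of polar pili and holdfast (1 higher). In none of these was a gene lower as deposited. After centring, 3 cell division genes were higher and 3 lower. Higher and lower calls there numbered 1 and 2 for outer membrane assembly and Tol-Pal, and 0 and 1 for DNA replication and repair. They numbered 0 and 0 for the S-layer, and 1 and 1 for polar pili and holdfast. Of 45 list tests, 9 had a median, a mean and a test that differed in sign, and none of these was called. In the difference between strains these were RNA polymerase and sigma factors, outer membrane assembly and Tol-Pal, DNA replication and repair, and genes without a symbol.

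The last question was whether long and short messages differed. Across 1193 coding genes the ratio in the full-length strain rose weakly with coding length, with a Spearman rho of 0.15 and 0.18 in the 2 cultures and 0.17 for their mean. Of 5 groups of shared genes by length, the shortest (median 391.5 nt) had a median ratio of 0.41 and the longest (2193 nt) of 0.52. In the ΔCTD strain rho was 0.02 and 0.06 over 2146 genes, and for the difference between strains it was 0.09. These 7 correlations are across genes, which are not independent replicates. Genes with a ratio were longer than those without, with a median of 1053 against 723 nt in the full-length strain and 951 against 624 nt in the ΔCTD strain.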

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

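The differences below were tested with limma as the full-length ratio minus the ΔCTD ratio. They are given where the difference passed in the same direction as deposited and relative to the median, a stricter criterion than the deposited values alone. The tests of explanations were chosen after the results were seen, except that of coding length. Of 65 named RNAs with ratios in both strains, 46 passed as deposited and 35 on both scales, 23 higher and 12 lower.

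Higher with full-length RNase E were 5S rRNA (2.28), CCNA_R0077 (2.07), CCNA_R0088 (1.63), lovR (1.21), CCNA_01995 (1.15), CCNA_03400 (1.13), CCNA_01834 (1.12), rplS (1.10), CCNA_03786 (1.08), ftsA (1.08), pleD (1.03), pilA (0.99) and CCNA_02906 (0.96). Also higher were CCNA_00699 (0.95), CCNA_03030 (0.94), pssZ (0.91), CCNA_R0042 (0.90), CCNA_R0098 (0.88), CCNA_00808 (0.86), CCNA_01749 (0.80), popZ (0.79), CCNA_03587 (0.74) and rpsU (0.69). Lower were cdzC (-0.95), CCNA_01043 (-0.60), cdzI (-0.58), CCNA_02763 (-0.49), CCNA_03553 (-0.49), CCNA_01944 (-0.48), cdzD (-0.48), CCNA_03703 (-0.45), CCNA_02817 (-0.42), CCNA_03995 (-0.41), CCNA_01445 (-0.40) and CCNA_03984 (-0.38). Against other genes, the difference was smaller for ribosomal proteins (camera, adjusted p = 0.00645), and larger for cell cycle regulators (adjusted p = 0.0104) and non-coding RNAs (adjusted p = 1.66e-10). On centred values camera gave adjusted p = 0.00059, 0.0088 and 0.00059 for these lists. With an estimated correlation these were adjusted p = 0.964, 0.964 and 0.704.

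The shared RNAs lay higher in the full-length eluates than in the ΔCTD eluates. A single scaling factor per library would move rRNA with the messages, yet the coding median rose above the mean of 23S and 16S rRNA by 0.41 more in the full-length strain (SD over cultures 0.0556; the second 23S row was not used). The median difference over these RNAs was at least 0.29 in each of the 4 pairs of cultures. Since the pattern is defined over the shared RNAs, this cannot test whether the choice of RNAs with ratios shaped it. The shared RNAs are 1191 of the 1207 with full-length ratios, and how an RNA came to have a ratio is not known. Dilution of ΔCTD eluates with unlabelled RNA stays open, since the profile of unlabelled RNA was not measured. The spread over genes was 0.679 of the full-length one (bootstrap over genes 0.616 to 0.745) and the median excess 0.173. Genes were resampled as if independent and with the cultures fixed, so the interval leaves out variation between cultures. The lowest full-length culture median lay 0.30 above the highest ΔCTD one, so a role of the C-terminal domain may remain, as a hypothesis that cannot be told apart from such dilution or other differences between the strains.

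Ribosomal protein messages had a low difference between strains. Of 26 genes 24 lie in 1 cluster, and the 2 outside it, rplS and rpsU, had a median difference of 0.90 against 0.08 inside, which may mean that the list reports 1 locus counted many times. With only 2 genes outside, and the row of rplS overlapping another, this rests on few values. Ribosomal protein genes without a symbol are not in the list, so the share inside the cluster is that of the listed genes alone. Lists matched on coding length had a typical median of 0.36, near the 0.37 of all shared RNAs, and 0.01% had a median as low. Genes of like length thus did not as a rule have a low difference. Members of the matched lists were drawn separately, while 24 of the 26 genes share 1 cluster. The 0.01% therefore overstates the evidence and does not decide on coding length.

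The RNAs highest in the full-length eluates were 5S rRNA and small RNAs. Better recovery of all short RNA would raise tRNAs too, but the tRNA median lay below the coding median in both full-length cultures, by -0.38 and -0.46, on 3 tRNAs. These tRNAs (76 to 86 nt) were shorter than 5S rRNA (118 nt), CCNA_R0088 (140 nt) and CCNA_R0077 (172 nt). They therefore cannot test better recovery of RNAs of that size. The smallest gap between a full-length and a ΔCTD culture over 5S rRNA and 6 small RNAs was 0.41, and 0.11 after centring. After centring 5S rRNA and 4 of the 6 small RNAs passed, while CCNA_R0061 fell from 0.65 (SE 0.14) to 0.26 (SE 0.11) and CCNA_R0123 from 1.11 (SE 0.14) to 0.73 (SE 0.24). A role of the C-terminal domain may remain, as a hypothesis that cannot be told apart from recovery by size or other differences between the strains.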

How the results depend on the processing

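Alternatives other than the 2-fold minimum, leaving out rRNA and tRNA, leaving out a culture, the estimated correlation and fry were chosen after seeing the data. Centring gave 246 higher and 274 lower (520 in all) with full-length RNase E, 217 and 246 in the ΔCTD strain, and 153 and 179 (332) for the difference. It moves each culture's median to 0 and also changed the estimated prior (SD 0.138 to 0.0889), and the effects of these on the counts were not separated. A 2-fold minimum left 16 and 0, 4 and 0, and 15 and 0. Lower calls of the difference numbered 14 as reported and 27 over the shared RNAs alone; the cause was not tested. Leaving out a culture gave 135 to 600 higher calls and 196 to 659 calls in all in the ΔCTD strain, the lowest without ΔCTD culture 2. A lone culture was assumed to vary like the other strain. The other counts stayed within 1.5 times.

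Replicate numbers are shared by the strains, but the deviations of same-numbered cultures correlated at 0.09 over 2 pairs, and the labels give no shared batch, so the numbers were not taken to pair the cultures. Both second cultures had the higher median of their strain and exactly repeated ratios (101 and 172, against 0 and 0), so something shared by them stays open. With a replicate block, the lower calls of the difference numbered 35, the other counts stayed within 1.5 times, and no list call changed. The block added calls for 11 of 114 named results and the shared RNAs alone for 10, and neither ended any. In the ΔCTD strain both added dnaK, gcrA, ftsZ and rpsU, and in the difference sciP, rsaA, hfq, ctrA, rplP and mucR2, with dnaK under the block alone.

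Among named results that passed as deposited or after centring, centring reversed the sign for rne (-0.027), dnaA (-0.067), dnaK (-0.028), ftsZ (-0.12), acnA (-0.0014) and CCNA_R0042 (-0.045) with full-length RNase E, and for rne (-0.31) and gcrA (-0.067) in the difference. Some that passed on neither scale also changed sign, such as ctrA (-0.126) and sciP (-0.0944) in the difference. Of 124 results for named RNAs, 22 calls ended and 9 were added under centring. Robust moderation returned identical values, so it tests nothing.

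With an estimated correlation all 5 list calls ended. The adjusted p (camera) was 0.804 for non-coding RNA in the full-length strain and 0.986 for ribosomal proteins in the ΔCTD strain. In the difference it was 0.964, 0.964 and 0.704 for ribosomal proteins, cell cycle regulators and non-coding RNA. No list in any comparison had a value below 0.70. The estimate holds shifts of whole cultures and was 0.26 even for 859 genes without a symbol. A call that ended there therefore does not show that a list matched other genes. The preset of 0.01 lies below every estimate, so neither setting decides. In the full-length strain fry, which was run on centred values, gave an adjusted p of 0.0765 for non-coding RNA. Of 40 list results not called, fry passed 4 and leaving out ΔCTD culture 2 passed 2. Over all ΔCTD ratios non-coding RNA turned upward (5.015e-06, or 0.00257 with 1 row per RNA), with more RNAs in the list, and was not called with an estimated correlation (0.992). Spearman's rho of length was 0.15 to 0.18 with a full-length culture left out, and 0.079 over the shared genes in the ΔCTD strain.

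Not run, for want of counts, were TMM, RLE and library totals, count and CPM filters, pseudocounts, DESeq2, voom, the fit without the culture block, the direct contrast of eluates and the lysate, class share and abundance results. Depth is unknown, so no result was weighed by it.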

Other observations

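The groups and tests in this part were chosen after the values were seen. The bounds that decide the tests of neighbouring and nuo genes were reworded, and the neighbour test was divided into 3 comparisons, after their results were seen. Values of 7 regulators of the general stress response are given without a test of the group. In the difference between strains, phyR (0.57), nepR (0.61), phyK (0.91), sigT (0.82), sigU (0.47), lovK (0.35) and lovR (1.21) passed the limma test as deposited, as did 728 of all 1191 shared RNAs in that direction. After centring 3 passed, lovR (0.83), phyK (0.53) and sigT (0.43), and lovK turned to -0.03. Of these genes phyK, sigT, nepR and phyR adjoin each other, as do lovR and lovK, and the rows of phyK and sigT each overlap 1 other row.

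Within the ribosomal protein cluster, secY, the gene of a protein translocation channel, differed by 0.74 between strains, or 0.36 relative to the median (limma, adjusted p = 0.0217). The neighbouring rpoA, an RNA polymerase subunit gene, stood at -0.20, or -0.59 relative to the median (adjusted p = 0.00813), and adk at 0.31 and -0.08. In both second cultures some ratios recurred exactly, 101 times with full-length RNase E and 172 times in the ΔCTD strain, against 0 in the first cultures.

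Shared transcripts may give neighbouring genes similar ratios. In the ΔCTD strain, adjacent genes on 1 strand under 50 nt apart (257 pairs) had a higher correlation than adjacent genes on opposite strands (100 pairs). The one-sided permutation test gave adjusted p = 0.0201 over 3 comparisons. No limit on distance was set for the opposite-strand pairs, and overlapping genes were not left out. The sets can thus differ in distance and overlap as well as strand, so the test cannot assign the higher correlation to shared transcripts. The permutation treated pairs as independent, though successive pairs can share a gene, and the ribosomal protein cluster was not left out. This p-value may therefore overstate the evidence. For full-length RNase E and for the difference the adjusted p was 0.109 each, which leaves the question open there. In the 14 nuo genes of respiratory complex I, 7 membrane-arm genes had a mean difference of 0.36 and 7 peripheral ones of 0.21, and the gap of 0.15 did not pass an exact two-sided permutation test (p = 0.224 over 3432 splits).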
